A study of Homo sapiens with 12 samples.

How the data were processed

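RNA of A549 cells was measured by sequencing in 12 libraries, 3 in each of 4 groups: empty vector (Co.vec) or LETS1, each with ligand buffer or TGF-β at 5 ng/mL for 4 h. Per the labels, cells were transduced overnight with lentivirus, then given puromycin, and the ligand was added after another 3 days. RNA was taken with a column kit and libraries were sequenced on a DNBSEQ instrument. The authors trimmed reads with cutadapt 2.10, aligned them with STAR 2.7.5a to GRCh38 and counted them per gene with HTSeq 0.12.4. The values deposited are raw counts, whole fragments per gene, in 60676 gene rows followed by 5 rows for fragments given to no gene. The strand setting and the annotation release behind the counts are not given in the sources used here. Symbols came from a gene name table, matched by gene id without the version for 60357 genes, and coordinates from GENCODE release 29 (GRCh38).

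Fragments counted in genes ran from 19705135 to 20351043 per library. Fragments in no annotated gene made up 2.81% to 3.53%, those matching several genes 10.1% to 10.9% and unaligned ones 2.93% to 4.27%. The closeness of replicates was checked as chi-square per degree of freedom between pairs of a group over genes with at least 20 counts in the pair (2.16 to 5.24 over 12 pairs), so spread between libraries exceeded counting error in every pair. Whether replicate numbers pair libraries across groups was checked by correlating residuals: 0 of 18 pairs exceeded 0.1, and replicates were treated as unpaired.

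Groups, comparisons, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. Genes were kept with filterByExpr of edgeR 4.0.16 in R 4.3.3, which left 16192. Library sizes were scaled by TMM, and a quasi-likelihood model with robust dispersion and 1 mean per group was fitted to all 12 libraries (median prior degrees of freedom 30). The 5 contrasts were LETS1 against Co.vec in buffer, LETS1 against Co.vec with TGF-β, TGF-β against buffer in Co.vec cells, TGF-β against buffer in LETS1 cells, and the interaction, the last ligand response minus the one before it. The p values were adjusted by Benjamini-Hochberg within each contrast, and genes with an adjusted p under 0.05 were called higher or lower. On simulated data with 200 genes changed, the model was tested for the calls it recovers: at log2 0.5 it called 71, 72, 74, 74 and 54 of 100 genes in the 5 contrasts, at log2 1.0 it called 84, 91, 91, 82 and 73 of 100, and it called 9, 17, 10, 16 and 6 of 15992 unchanged genes.

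Named genes were the 8 largest rises and 8 largest falls of each two-group contrast (5 and 5 for the interaction), among genes with a symbol, an adjusted p under 0.05, a mean CPM of at least 1 in the higher group and every library of a group above every library of the other. For the interaction the adjusted p alone was required. To these were added TGFBR1, SMAD7, NFAT5, NR4A1, CCN2, PMEPA1, SNAI1, SNAI2, CDH1, CDH2, VIM, FN1 and SKIL, and 2 to 4 members of each list described. Another gene fixed in advance by name is not reported here, though the counts and list tests include it. Log2 fold changes came from the fitted model, their standard errors (SE) were the log2 fold change over the square root of its F statistic, and CPM used TMM-scaled library sizes. Where a group had 0 counts, a floor was given from 3 counts over the group, and where it had 1 to 3 counts, a ratio with a 95% counting interval.

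The 26 lists, with 657 genes of which 597 were measured, were written from general knowledge: early target genes of TGF-β and SMADs, TGF-β pathway components, BMP and ID targets, mesenchymal genes, epithelial genes, extracellular matrix genes, NFAT5 targets, NR4A and immediate early genes, type I interferon genes, NF-κB and cytokine genes, YAP/TAZ targets, p53 targets, mitosis genes, DNA replication genes, NRF2 targets, cholesterol synthesis genes, ATF4 targets, endoplasmic reticulum chaperones, heat shock protein genes, hypoxia genes, migration and protease genes, lung epithelial and A549 lineage genes, markers of other cell types, mitochondrially encoded genes, cytosolic ribosomal protein genes and replication-dependent histone genes. Some lists share genes. Each was tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01 and adjusted by Benjamini-Hochberg over the 26 lists of a contrast. Members were also adjusted over the list alone.

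Alternatives tried were RLE size factors, no filter on low counts, a block for replicate number, leaving out each of the 12 libraries in turn, a log2 fold change of at least 1, DESeq2 1.42.0 with a Wald test, a fit of the 6 libraries compared alone, camera with the correlation estimated from the data, and fry of limma. The list of TGF-β and SMAD targets without 5 early response members was added after seeing the data. Standard errors of summaries over genes are jackknife errors over left-out libraries. The level of LETS1 was left out because 0 genes carried that symbol or alias, and reads were not used here, so the transgene, vector sequences, splicing and variants were not analysed here.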

Results

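RNA from A549 cells, an established human lung adenocarcinoma line, was sequenced in 12 libraries that form 4 groups of 3. The cells carried either an empty lentiviral vector (Co.vec) or the vector expressing LETS1, a long non-coding RNA, and received ligand buffer or 5 ng/mL TGF-β for 4 h. Fragments counted in genes numbered 19705135 to 20351043 per library, 80.0% to 81.1% of the 24545791 to 25109420 fragments counted in all, and 16192 genes passed the filter on low counts. Counts of replicate pairs differed by 2.16 to 5.24 times the variance that counting alone would give (chi-square per degree of freedom, 12 pairs), and the common biological coefficient of variation was 0.0413. The first principal component held 49.4% of the variance and parted the 6 buffer libraries from the 6 given TGF-β, while the second held 21.5% and parted Co.vec from LETS1. The labels call the replicates biological and do not say whether each came from its own transduction, so every p value measures only the spread between these samples. Intervals and floors given for single genes cover counting error only, and reads copied in amplification would widen them. The symbol tables held 0 genes named LETS1, by symbol or listed alias, and the level of the overexpressed transcript was not checked here.

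The comparison of LETS1 with Co.vec in buffer asks which genes differ when LETS1 is expressed without added ligand. PCDH10, a protocadherin (ENSG00000138650, GRCh38 chromosome 4, 133149315 to 133208606), rose from 0.861 ± 0.171 to 29.7 ± 1.61 CPM (library-scaled counts, mean ± SD, n = 3 per group). This was a log2 fold change of 5.10 (SE 0.148, edgeR adjusted p = 1.39e-25). CDH11, a cadherin of mesenchymal cells (ENSG00000140937, chromosome 16, 64943753 to 65126112), rose from 0.0996 ± 0.0504 to 6.75 ± 1.08 CPM (n = 3). Its log2 fold change was 6.0 (SE 0.282, adjusted p = 1.25e-19). NTS, which encodes the peptide neurotensin (ENSG00000133636, chromosome 12, 85874295 to 85882992), fell from 218.3 ± 4.18 to 41.1 ± 3.57 CPM (n = 3). That was a log2 fold change of -2.41 (SE 0.055, adjusted p = 7.28e-30). EGR1, an immediate early transcription factor (ENSG00000120738, chromosome 5, 138465490 to 138469315), rose from 2.42 ± 0.255 to 66.7 ± 15.6 CPM (n = 3), a log2 fold change of 4.78 (SE 0.217, adjusted p = 3.83e-08). PMEPA1, a SMAD target that dampens TGF-β signalling (ENSG00000124225, chromosome 20, 57648392 to 57711536), rose from 187.9 ± 5.74 to 256.3 ± 13.9 CPM (n = 3), a log2 fold change of 0.45 (SE 0.046, adjusted p = 5.25e-10).

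Across the genome, 1387 genes were higher and 1062 lower with LETS1 in buffer (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), of which 227 and 140 changed at least 2-fold. SGCZ and PCP4 had 0 counts in the Co.vec buffer libraries and were at least 27.2-fold and at least 23.6-fold higher with LETS1, against a floor of 3 counts over the group. ANKRD30B, which has the close paralog ANKRD30A, was 83.3 times as high (95% counting interval 28.2 to 407), and the GABA receptor gene GABRA2 was 69.9 times as high (23.6 to 342). FOSB (log2 fold change 5.42) and the glutamate transporter gene SLC1A3 (5.23) completed the 8 largest rises. The 8 largest falls included the mucin gene MUC16 (-3.51), SERPINB5 (-3.41), the gut keratin gene KRT20 (-2.46), the chemokine gene CX3CL1 (-2.46) and the immune checkpoint gene VTCN1 (-2.18). Of genes in TGF-β signalling, the receptor gene TGFBR1 rose from 58.5 ± 4.23 to 73.5 ± 6.41 CPM (n = 3; log2 fold change 0.33, adjusted p = 2.77e-05), and the inhibitory SMAD gene SMAD7 rose by 0.65 on the log2 scale (adjusted p = 3.92e-08). NFAT5 had a log2 fold change of -0.06 (adjusted p = 0.612), CCN2 of -0.08 (0.513), SKIL of 0.03 (0.769), CDH1 of 0.03 (0.799) and SNAI2 of 0.76 (0.0799), and none of these 5 passed. VIM had a log2 fold change of 0.11 (adjusted p = 0.0785) and passed when Co.vec buffer replicate 3 was left out (adjusted p = 0.0263).

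**Figure D1:**
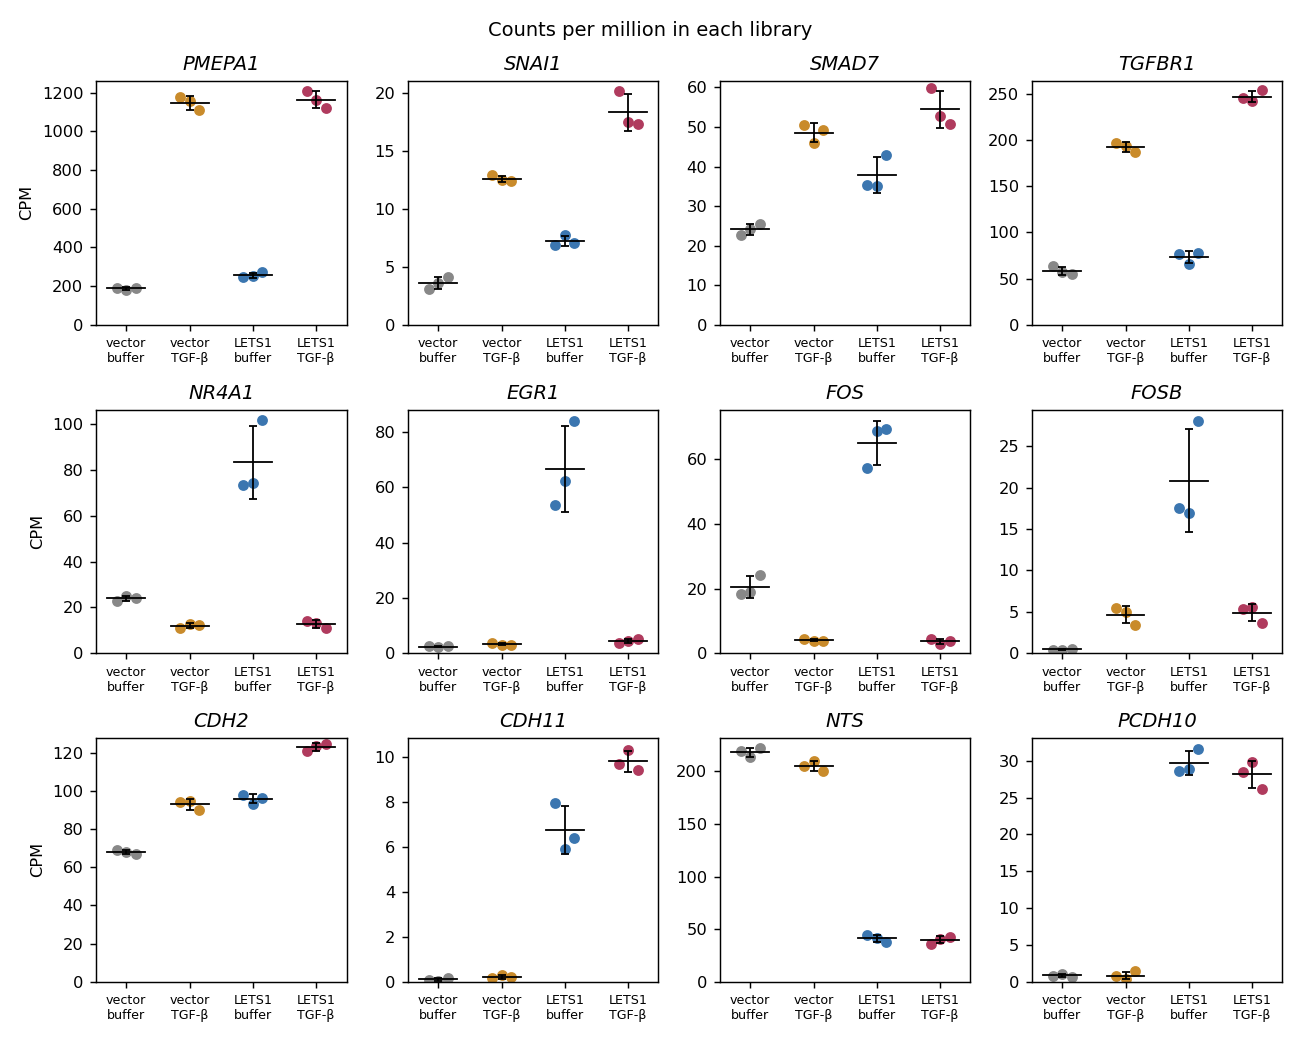
CPM in each library for 12 genes, with 1 point per library, 4 groups of 3 on the horizontal axis, a line at each group mean and bars of 1 SD; vertical axes are linear and start at 0. PMEPA1 sat at 187.9 CPM with Co.vec in buffer and 256.3 with LETS1 in buffer, and EGR1 reached 66.7 CPM with LETS1 in buffer against 2.42 to 4.33 in the other groups.

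Of the 24 measured immediate early genes, which respond to stimuli within minutes to hours, 20 rose, 2 fell and 2 did not pass, with 20 and 2 adjusted over the list alone. The camera adjusted p was 7.29e-48 (adjusted p = 0.00594 with an estimated correlation). NR4A1, an orphan nuclear receptor (ENSG00000123358, chromosome 12, 52022832 to 52059507), rose from 23.9 ± 1.25 to 83.3 ± 16.0 CPM (n = 3; log2 fold change 1.80, adjusted p = 3.91e-07), and DUSP1 (1.70), FOS (1.67) and ATF3 (1.63) rose with it. Of the 20, 18 were highest in LETS1 buffer replicate 3. Of the 34 measured early target genes of TGF-β and SMADs, 22 rose, 0 fell and 12 did not pass (23 and 0 adjusted over the list alone). Their mean log2 fold change was 0.44 (camera adjusted p = 2.7e-23; adjusted p = 0.0197 with an estimated correlation). Examples were GADD45B (1.79), KLF10 (0.81) and BHLHE40 (0.64), which like JUNB and RHOB are also early response genes. Without those 5, an alternative chosen after seeing the data, 17 of 29 members rose and 0 fell (camera adjusted p = 8.08e-13; adjusted p = 0.0316 with an estimated correlation). Of 32 TGF-β pathway components, 5 rose, 3 fell and 24 did not pass (camera adjusted p = 0.592), TGFB2 (0.63) and TGFB1 (0.40) among the rises and TGFBR3 (-0.60) among the falls. Of 11 BMP and ID targets, 5 rose, among them ID3 (0.57) and ID1 (0.49), and 2 fell (camera adjusted p = 0.00265; adjusted p = 0.208 with an estimated correlation).

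Mesenchymal genes moved up and epithelial genes down with LETS1 in buffer. Of 21 measured mesenchymal genes, 10 rose, 1 fell and 10 did not pass (14 and 1 adjusted over the list alone; camera adjusted p = 5e-11; adjusted p = 0.00533 with an estimated correlation). SPARC (1.78), SNAI1 (1.01), the N-cadherin gene CDH2 (0.49) and FN1 (0.30) were among the rises. The mean of 0.65 exceeded the median of 0.33, and CDH11 is on this list. Of 19 epithelial genes, 1 rose and 9 fell (1 and 11 adjusted over the list alone; camera adjusted p = 2.63e-07; adjusted p = 0.00477 with an estimated correlation). Among the falls were the keratin genes KRT19 (-0.79), KRT18 (-0.55) and KRT8 (-0.37) and the tight junction gene TJP3 (-0.93), while the E-cadherin gene CDH1 did not pass. KRT8 and KRT18 have many pseudogenes, whose reads the counts do not set apart. Of 23 extracellular matrix genes, 16 rose and 1 fell (17 and 1 adjusted over the list alone; camera adjusted p = 1.66e-10; adjusted p = 0.0197 with an estimated correlation). COL5A1 (0.61) and COL6A1 (0.69) were among the rises and LAMB3 (-0.66) was the fall. Of 15 lung epithelial and A549 lineage genes, 0 rose and 7 fell (1 and 7 adjusted over the list alone; camera adjusted p = 1.05e-19; adjusted p = 0.00477 with an estimated correlation). The mucin genes MUC5AC (-1.92) and MUC5B (-1.23) and AGR2 (-0.83) led the falls. The mean was -0.45 and the median -0.15. Of the 25 lung and lineage genes listed, SFTPB, SFTPC and NKX2-1 were among those with too few counts to test.

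Of 23 YAP/TAZ targets, 11 rose and 2 fell (camera adjusted p = 3.72e-06; adjusted p = 0.0204 with an estimated correlation). CCN1 (1.22) and IGFBP3 (0.71) were among the rises. Of 23 NRF2 targets, 1 rose and 10 fell (camera adjusted p = 8.98e-05; adjusted p = 0.0204 with an estimated correlation). ALDH3A1 (-0.52) and AKR1C1 (-0.34), the latter with the close paralog AKR1C2, were among the falls and HMOX1 (0.59) was the rise. Of 28 ATF4 targets, 6 rose and 2 fell (camera adjusted p = 0.00643; adjusted p = 0.0316 with an estimated correlation). The mean of 0.14 exceeded the median of 0.01. PPP1R15A (0.75), STC2 (0.62) and ATF3 were among the rises, and ATF3 is also on the list of immediate early genes. NF-κB and cytokine genes (9 of 24 rose, 1 fell, camera adjusted p = 0.000151) and mitosis genes (14 of 30 rose, 0 fell, camera adjusted p = 5.86e-05) each had an adjusted p = 0.194 with an estimated correlation. Cholesterol synthesis genes (10 of 24 rose, 1 fell, camera adjusted p = 0.00348) had an adjusted p = 0.366 with an estimated correlation. DNA replication genes (6 of 30 rose, 0 fell, camera adjusted p = 0.0178) had an adjusted p = 0.388 with an estimated correlation. Targets of p53 (6 of 28 rose, 1 fell, camera adjusted p = 0.033) and endoplasmic reticulum chaperones (0 of 19 rose, 6 fell, camera adjusted p = 0.00233) each had an adjusted p = 0.076 with an estimated correlation. Of 41 cytosolic ribosomal protein genes, 7 fell (camera adjusted p = 0.00769; adjusted p = 0.599 with an estimated correlation). Left-out libraries ended 3 of these camera calls: LETS1 buffer replicate 1 for p53 targets (adjusted p = 0.0562), LETS1 buffer replicate 2 for DNA replication (0.0551) and Co.vec buffer replicate 3 for ribosomal proteins (0.144).

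The other lists did not pass in buffer with camera. These were NFAT5 targets (3 of 14 rose, 2 fell, camera adjusted p = 0.991), type I interferon genes (1 of 36 rose, 2 fell, 0.774), hypoxia genes (4 of 25 rose, 1 fell, 0.179), replication-dependent histone genes (0 of 13 rose, 2 fell, 0.152) and mitochondrially encoded genes (0 of 13 rose, 0 fell, 0.991). Heat shock protein genes (4 of 16 rose, 0 fell, camera adjusted p = 0.152) and migration and protease genes (6 of 25 rose, 4 fell, 0.0914) passed when LETS1 buffer replicate 1 was left out (0.0357 and 0.029). With fry, hypoxia genes (adjusted p = 0.00202), replication-dependent histone genes (0.0142) and migration and protease genes (0.0179) passed. Of the 21 markers of other cell types, 6 had enough counts to test and LUM alone rose (log2 fold change 2.17, to 1.14 ± 0.419 CPM, n = 3), with a camera adjusted p of 0.736 for the list.

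The comparison of LETS1 with Co.vec after 4 h of TGF-β asks which genes differ when LETS1 is expressed in stimulated cells. PCDH10 was again higher, at 28.2 ± 1.83 against 0.846 ± 0.508 CPM (n = 3; log2 fold change 5.04, SE 0.151, edgeR adjusted p = 3.98e-25), as was CDH11 at 9.81 ± 0.477 against 0.221 ± 0.0795 CPM (log2 fold change 5.43, SE 0.226). NTS was lower, at 39.8 ± 3.27 against 205.1 ± 4.66 CPM (n = 3; log2 fold change -2.37, SE 0.056, adjusted p = 1.08e-29), as were SERPINB5 (-4.11), KRT20 (-2.75), the actin-bundling gene VIL1 (-2.36) and VTCN1 (-2.37). TGFBR1 rose by 0.36 on the log2 scale (adjusted p = 6.82e-07). PMEPA1 (0.02, adjusted p = 0.814), SMAD7 (0.16, 0.112) and NR4A1 (0.08, 0.829) did not pass. SPINK6 had 0 counts with Co.vec and was at least 20.9-fold higher with LETS1, against a floor of 3 counts over the group. In all, 1227 genes were higher and 1052 lower, of which 201 and 107 changed at least 2-fold.

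Mesenchymal genes rose (13 of 21, 1 fell; 15 and 1 adjusted over the list alone; camera adjusted p = 7.81e-14; adjusted p = 0.00385 with an estimated correlation). SPARC (2.58), CDH2 (0.40), SNAI1 (0.54) and VIM (0.18) were among them. The mean of 0.63 exceeded the median of 0.35. Epithelial genes fell (9 of 19, 0 rose; 10 and 1 adjusted over the list alone; camera adjusted p = 3.77e-08; adjusted p = 0.00385 with an estimated correlation). KRT19 (-0.68) and ELF3 (-0.72) were among them, and CDH1 stood at 0.06 (adjusted p = 0.48). Lung epithelial and A549 lineage genes went both ways (4 of 15 fell, 3 rose; 6 and 4 adjusted over the list alone). The test was downward (camera adjusted p = 7.3e-11; adjusted p = 0.0109 with an estimated correlation). The mean was -0.34 and the median -0.06, with MUC5AC (-1.95) and MUC5B (-1.20) the largest falls. Early targets of TGF-β and SMADs were split into 15 that rose, 2 that fell and 17 that did not pass (16 and 2 adjusted over the list alone), with a camera adjusted p of 4.72e-07 and an adjusted p = 0.202 with an estimated correlation. ETS2 (0.48) and TPM1 (0.45) were among the rises. Extracellular matrix genes (14 of 23 rose, 1 fell, camera adjusted p = 3.77e-08) had an adjusted p = 0.0591 with an estimated correlation. Mitosis genes (16 of 30 rose, 0 fell, 1.03e-07) had an adjusted p = 0.136 with an estimated correlation, and type I interferon genes (10 of 36 rose, 1 fell, 0.00924) an adjusted p = 0.219 with an estimated correlation. NF-κB and cytokine genes (10 of 24 rose, 2 fell, camera adjusted p = 8.84e-06) and DNA replication genes (10 of 30 rose, 0 fell, 0.000426) also passed. So did NRF2 targets (1 of 23 rose, 8 fell, camera adjusted p = 0.00212) and endoplasmic reticulum chaperones (0 of 19 rose, 7 fell, 0.00253). With an estimated correlation these lists had camera adjusted p values of 0.191, 0.219, 0.0916 and 0.133. Immediate early genes did not pass (2 of 24 rose, 1 fell; mean log2 fold change 0.02, camera adjusted p = 0.849). NFAT5 (log2 fold change -0.20, adjusted p = 0.0305) lost its call when any 1 of the 6 libraries compared was left out (adjusted p = 0.0577 to 0.0963). SNAI2 (0.61, 0.0368) did so when any 1 of 5 libraries was left out (0.056 to 0.177), and CCN2 (-0.16, 0.0488) when any 1 of 7 was left out (0.050 to 0.186). With DESeq2 none of these 3 passed (NFAT5 0.0501, SNAI2 0.138, CCN2 0.096), and CCN2 also failed with RLE size factors (0.0566) and with the replicate block (0.0504).

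The calls of both LETS1 comparisons overlapped: 772 genes were higher in both against 105.1 expected if independent, 583 were lower in both against 69.0 expected, and 6 were called in opposite directions. Across the 3367 genes called in either comparison, the Pearson correlation of the log2 fold changes was 0.869 (jackknife SE 0.0188 over libraries). It is a correlation across genes, which are not independent replicates. The comparisons share no library, but the labels do not say whether their cells came from separate transductions. A fixed difference between the Co.vec and LETS1 populations would recur in both. With no filter on low counts the correlation was 0.749.

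**Figure D2:**
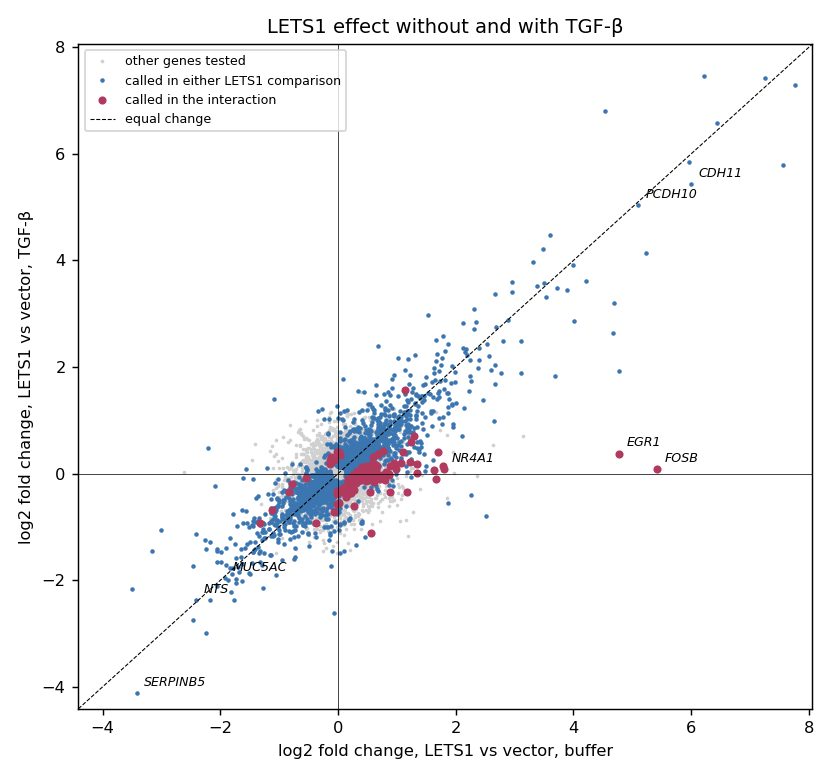
Log2 fold change of LETS1 against Co.vec with TGF-β (vertical) against that in buffer (horizontal), with 1 point per gene tested, coloured where called in either comparison or in the interaction. PCDH10 (5.10 and 5.04) and CDH11 (6.0 and 5.43) lie near the diagonal, and EGR1 (4.78 and 0.38) and FOSB lie far to its right.

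The comparison of TGF-β with buffer in Co.vec cells asks which genes respond to the ligand without LETS1. PMEPA1 rose from 187.9 ± 5.74 to 1147 ± 35.0 CPM (n = 3; log2 fold change 2.61, SE 0.047, edgeR adjusted p = 7.96e-34). TGFBR1 (1.72), SKIL (1.65), CCN2 (2.06), SNAI1 (1.81), SMAD7 (1.01) and CDH2 (0.45) rose, and CDH1 fell from 95.9 ± 3.72 to 71.3 ± 4.39 CPM (n = 3; log2 fold change -0.43, adjusted p = 4.17e-09). The largest rises included those of LEFTY2, a secreted TGF-β family antagonist, at 104 times (95% counting interval 18.2 to 4140), CGB8, from a cluster of near-identical paralogs, at 66.7 times (18.1 to 557), and the lipase inhibitor gene ANGPTL4 (log2 fold change 4.53). The largest falls included DEPP1 (-3.91), the clock output gene DBP (-2.69), FOS (-2.35) and the stem cell transcription factor gene SOX2. SOX2 went from 13.1 ± 0.815 to 2.63 ± 0.518 CPM (n = 3; log2 fold change -2.31, edgeR adjusted p = 1.25e-17). In all, 3416 genes were higher and 3011 lower, of which 618 and 284 changed at least 2-fold.

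Of the 34 early targets of TGF-β and SMADs, 32 rose and 0 fell (32 and 0 adjusted over the list alone; camera adjusted p = 7.62e-102; adjusted p = 0.00086 with an estimated correlation). PDGFB (3.59) and COL4A1 (1.72) were among them. Migration and protease genes rose (20 of 25, 2 fell; camera adjusted p = 5.99e-19; adjusted p = 0.00501 with an estimated correlation), as did extracellular matrix genes (15 of 23, 2 fell; 9.33e-17; adjusted p = 0.00547 with an estimated correlation), with ADAM19 (2.75) and COL1A1 (3.24) as examples. Mesenchymal genes rose (14 of 21, 1 fell; camera adjusted p = 9.54e-12; adjusted p = 0.00501 with an estimated correlation). FN1 was among them (log2 fold change 0.18, adjusted p = 0.0106) and lost its call without Co.vec buffer replicate 3 (0.06) or Co.vec TGF-β replicate 3 (0.0679). Epithelial genes went both ways (6 of 19 rose, 5 fell; camera adjusted p = 0.871), with CLDN4 (2.36) among the rises and ELF3 (-1.22) among the falls. DNA replication genes (21 of 30 fell, 1 rose, camera adjusted p = 2.69e-06) had an adjusted p = 0.137 with an estimated correlation, and mitosis genes (20 of 30 fell, 1 rose, 0.000524) an adjusted p = 0.264 with an estimated correlation. Immediate early genes (14 of 24 rose, 6 fell, camera adjusted p = 0.000345) had an adjusted p = 0.362 with an estimated correlation. For hypoxia genes (9 of 25 rose, 5 fell) the mean was 0.23, the median -0.05 and the test upward (camera adjusted p = 0.0299; adjusted p = 0.121 with an estimated correlation), and the call was lost without Co.vec buffer replicate 1 (0.053).

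The comparison of TGF-β with buffer in LETS1 cells asks which genes respond to the ligand when LETS1 is expressed. PMEPA1 rose from 256.3 ± 13.9 to 1163 ± 44.7 CPM (n = 3; log2 fold change 2.18, SE 0.046, edgeR adjusted p = 2.81e-31). TGFBR1 (1.75), SKIL (1.65), CCN2 (1.99) and SNAI1 (1.34) rose, and CDH1 fell (-0.39). Of 24 immediate early genes, 14 fell and 8 rose (camera adjusted p = 7.31e-05; adjusted p = 0.366 with an estimated correlation). NR4A1 fell from 83.3 ± 16.0 to 12.8 ± 1.63 CPM (n = 3; log2 fold change -2.70, adjusted p = 4.59e-09). In Co.vec cells NR4A1 was also lower with the ligand, at 11.098 to 12.882 CPM against 22.584 to 25.081 CPM in buffer (n = 3). In LETS1 cells EGR1 (-3.94) and FOS (-4.12) fell too. NR4A1AS, antisense to NR4A1 by name, was 80.0 times lower (95% counting interval 14 to 3200), where the strand setting of the counting is not given in the sources used here. In all, 3187 genes were higher and 3085 lower, of which 555 and 344 changed at least 2-fold. Of the early targets of TGF-β and SMADs, 29 of 34 rose and 3 fell, namely KLF10 (-0.53), LIF (-0.32) and RHOB (-0.31), with 29 and 3 adjusted over the list alone (camera adjusted p = 1.86e-78; adjusted p = 0.00176 with an estimated correlation). Mesenchymal genes rose (16 of 21, 0 fell; camera adjusted p = 1.97e-13; adjusted p = 0.00421 with an estimated correlation).

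The ligand responses of Co.vec and LETS1 cells shared 2686 genes that rose against 672.4 expected if independent and 2110 that fell against 573.7, with 18 in opposite directions. Across the 4796 genes called in both with the same direction, of 4814 called in both, the median ratio of the LETS1 to the Co.vec response was 0.981 (jackknife SE 0.0809). In buffer, the mean log2 fold change with LETS1 of the 2686 ligand-raised genes was 0.0886 (jackknife SE 0.0357) and the median 0.0415. For the 2110 ligand-lowered genes the mean was -0.00453 (SE 0.032) and the median, of opposite sign, 0.00724.

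**Figure D3:**
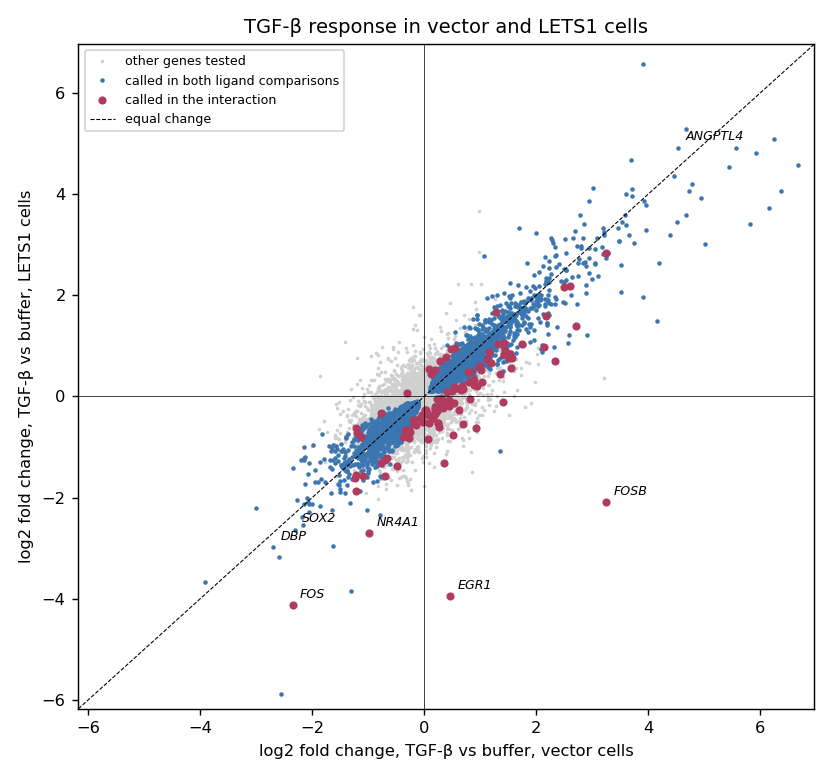
Log2 fold change of TGF-β against buffer in LETS1 cells (vertical) against that in Co.vec cells (horizontal), with 1 point per gene tested, coloured where called in both comparisons or in the interaction. ANGPTL4 (4.53 with Co.vec and 4.92 with LETS1) lies near the diagonal, and EGR1 (0.46 and -3.94) lies far under it.

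The interaction asks whether the ligand response differed between LETS1 and Co.vec cells, as the response with LETS1 minus that with Co.vec. The response of FOSB was lower by far with LETS1 (difference of log2 fold changes -5.34, SE 0.548, edgeR adjusted p = 0.000944), as were those of EGR1 (-4.41, SE 0.434, adjusted p = 0.000628), FOS (-1.77, SE 0.212) and NR4A1 (-1.72, SE 0.215, adjusted p = 0.00163). With TGF-β, EGR1 stood at 3.34 ± 0.458 CPM with Co.vec and 4.33 ± 0.701 CPM with LETS1 (n = 3). The response of PMEPA1 was smaller with LETS1 (-0.43, SE 0.063, adjusted p = 3.61e-05). That of SMAD7 was smaller too (-0.49, SE 0.102, adjusted p = 0.00846), a call lost without LETS1 buffer replicate 3 (adjusted p = 0.0653). TGFBR1 (0.03, adjusted p = 0.976), SNAI1 (-0.47, 0.24), CDH2 (-0.09, 0.841) and SKIL (0.00, 0.997) did not pass.

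In all, the interaction was negative for 97 genes and positive for 13, and 1282 genes had an unadjusted p under 0.05. Of the 97, 77 were called higher and 1 lower with LETS1 in buffer, where a negative interaction favours rises by construction, and 10 were called higher and 26 lower with LETS1 under the ligand. The positive genes included C2orf72 (0.59), the secretory regulator gene XBP1 (0.48), SLFN5 (0.45) and CDH6 (0.44). Immediate early genes held 18 of 24 members with a negative interaction and 0 with a positive one (19 and 0 adjusted over the list alone; camera adjusted p = 1.28e-114; adjusted p = 0.00114 with an estimated correlation). YAP/TAZ targets held 5 of 23 and 0 (8 and 1 adjusted over the list alone; camera adjusted p = 1.25e-11; adjusted p = 0.00907 with an estimated correlation), CCN1 (-0.997) and AMOTL2 (-0.47) among them. Early targets of TGF-β and SMADs held 8 of 34 and 0 (13 and 1 adjusted over the list alone; camera adjusted p = 1.97e-18; adjusted p = 0.0654 with an estimated correlation). For ATF4 targets (0 of 28 positive, 2 negative) the mean was -0.07, the median 0.01 and the test downward (camera adjusted p = 0.0393; adjusted p = 0.0932 with an estimated correlation), and the call was lost when any 1 of 7 libraries was left out (0.0546 to 0.104). Of the 23 YAP/TAZ targets, 14 rose and 4 fell with the ligand in Co.vec cells (camera adjusted p = 3.12e-09, 0.00779 with an estimated correlation). In LETS1 cells 11 rose and 4 fell (camera adjusted p = 0.000984, 0.103 with an estimated correlation). Under the ligand, 5 rose and 7 fell with LETS1 against Co.vec (camera adjusted p = 0.87). The count of 13 positive interactions became 8 without LETS1 buffer replicate 3, 21 without Co.vec TGF-β replicate 3 and 28 with no filter on low counts.

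**Figure D4:**
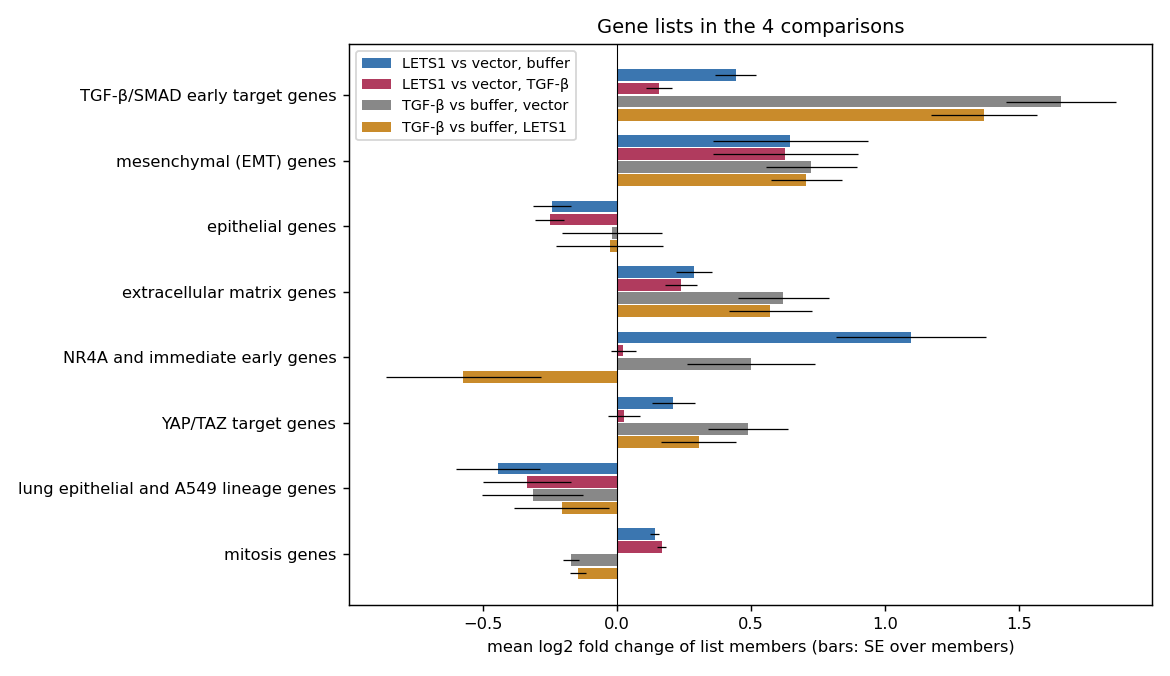
Mean log2 fold change of the measured members of 8 gene lists (vertical list names, horizontal axis in log2 units) in the 4 comparisons, with bars of 1 standard error over members. Immediate early genes stood at 1.10 with LETS1 in buffer and 0.02 with LETS1 and TGF-β, while mesenchymal genes stood at 0.65 and 0.63. The medians of the mesenchymal genes, CDH11 among them, were 0.33 and 0.35.

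Over all 5 comparisons, mean, median and camera direction differed in sign in 15 of the 130 results for lists, and 2 of those, the hypoxia and ATF4 results given above, were past the threshold.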

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

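The tests of a single outlying library, of normalization, of handling, of populations that differ, of a ceiling, of early response members and of simulated additive effects were chosen only after the results were seen; the exchanges of labels and the copy number test were set before.

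The first pattern is the loss with TGF-β of the LETS1 rise of immediate early genes: their mean interaction was -1.07, with FOSB at -5.34, EGR1 at -4.41, FOS at -1.77 and NR4A1 at -1.72, each noted because the ligand response differed between the vectors. A single outlying library is unlikely, since 19 of 24 members were still called higher without LETS1 buffer replicate 3, although 18 of the 20 called were highest in that library. Normalization is unlikely as the whole cause, since a size factor shifts all genes alike and at most 7 of the 24 members lay within 2 standard errors of any single shift. It was the last of 3 tests of normalization tried, its bounds set with the fold changes known; the list mean with RLE size factors (1.095) and its excess over the median of all genes (1.088) decided nothing. A difference in handling or harvest of the LETS1 dishes given buffer could produce the same pattern, and the list mean of 0.023 with the ligand does not separate it from an effect of LETS1 that TGF-β removes.

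The second pattern is the set of genes near silent with the empty vector and expressed with LETS1, such as PCDH10 and CDH11. A copy number difference over wide regions is unlikely for most of them. The nearest tested genes outside the set had a median log2 fold change of 0.013 in buffer (median over members, highest 0.235). Other members were left out of the neighbours, though some lie close together, such as FPR1 and FPR2. A difference limited to a short stretch is therefore not excluded. Populations that differ for reasons other than LETS1 could give the same result: 0 members passed the interaction test, which either account allows, and separate transductions would be needed to tell them apart.

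The next pattern is the smaller ligand response of early TGF-β and SMAD targets with LETS1, a list mean of -0.29 (camera adjusted p = 1.97e-18; adjusted p = 0.0654 with an estimated correlation). SMAD7 stood at -0.49 (lost without LETS1 buffer replicate 3, adjusted p = 0.0653) and PMEPA1 at -0.43. Whether a ceiling on the level with ligand contributes was not decided. The 8 members called differed by a mean of 0.099 (SE 0.056 over members) with the ligand and by 0.83 in buffer. They were picked for a negative interaction, which makes the difference with the ligand the smaller one by construction. Early response genes in the list may carry part of it: without 5 of them the mean was -0.175, still past the threshold (camera adjusted p = 0.000161) except with an estimated correlation (adjusted p = 0.289), where the whole list did not pass either. A difference in handling or harvest of the LETS1 dishes given buffer, named above, could also produce this pattern. It was not tested for these targets.

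Other results noted for a ligand response that differed between the vectors were the 13 genes with a positive and 97 with a negative interaction, C2orf72 (0.59), XBP1 (0.48), SLFN5 (0.45), CDH6 (0.44), SPDEF (0.44, lost without LETS1 TGF-β replicate 2, adjusted p = 0.0548) and SCHIP1 (-1.67, lost without LETS1 TGF-β replicate 1, adjusted p = 0.0683). The list mean of YAP/TAZ targets (-0.18), noted for the same reason, also passed with an estimated correlation (adjusted p = 0.00907). Those of BMP and ID targets (-0.29, adjusted p = 0.164 with an estimated correlation), cholesterol synthesis (-0.17, 0.0932), type I interferon (0.14, 0.0921), lung lineage (0.11, 0.0932) and cytosolic ribosomal proteins (0.086, 0.399) did not. Migration and protease genes (-0.22, adjusted p = 0.289 with an estimated correlation) and NFAT5 targets (-0.108, 0.0932) lost their calls also when any 1 of 2 (0.0718 to 0.104) and of 5 libraries (0.0638 to 0.111) was left out. ATF4 targets (-0.0699, 0.0932) and extracellular matrix genes (-0.0487, 0.399) did so for 7 (0.0546 to 0.104) and 4 libraries (0.0591 to 0.292). Unaligned fragments, a part of the data not analysed here, were more frequent with TGF-β, at 4.08% with Co.vec (3.35 ± 0.0843% in buffer, n = 3) and 3.89% with LETS1 (3.27 ± 0.465%).

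Exchanging labels among the 6 libraries of each two-group comparison gives 10 splits, too few for a share under 0.05. The real split alone (1 of 10 in each) reached its count, 2449, 2279, 6427 and 6272 genes, against at most 1 gene in any other. Every other split mixes libraries of both real groups, which widens the spread within groups. Few calls there were fixed in advance and say nothing about chance. For the interaction, 6 of 100 assignments, the real included, called at least its 110 genes, and the highest other called 3957. That share is not under 0.05, so this planned test does not exclude chance. The 5 others exchanged unequal numbers of libraries in buffer and with ligand, so LETS1's own effect, a structure of the samples, entered their interaction. Of 20 data sets simulated with additive effects and no interaction, the most called 2 genes. Genes were drawn independently there, with the spread estimated from these libraries. The simulation therefore holds no shift shared by many genes of a library, and it excludes nothing alone.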

How the results depend on the processing

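A log2 fold change of at least 1 left 227 higher and 140 lower genes with LETS1 in buffer, 201 and 107 with LETS1 and TGF-β, 618 and 284 with TGF-β in Co.vec cells, 555 and 344 in LETS1 cells, and 0 and 12 in the interaction. The 13 genes with a positive interaction became 28 with no filter on low counts, 8 without LETS1 buffer replicate 3 and 21 without Co.vec TGF-β replicate 3. The correlation of both LETS1 effects became 0.749 with no filter. With an estimated correlation, 9, 3, 6, 5 and 2 lists passed in the 5 contrasts in place of 17, 11, 13, 10 and 12, and with fry 18 passed for TGF-β in LETS1 cells and 7 in the interaction. DESeq2 gave no adjusted p for 3453 genes in the interaction. No alternative reversed a direction that had been called. The cause was not tested.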

Other observations

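The gene lists here were chosen after seeing the data, some members from these data, so their p values overstate the evidence. Of 15 measured mucous and gut secretory genes, 13 were lower and 1 higher with LETS1 in buffer (mean log2 fold change -1.38, camera p = 8.12e-126; p = 8.38e-08 with an estimated correlation), and the counts were 13 and 1 with TGF-β (-1.32). CEACAM6 fell from 493.3 to 184.6 CPM (log2 fold change -1.42, SE 0.045), and FCGBP (-1.79) and MUC13 (-1.29) fell too, while CEACAM5 rose (0.95). Of 15 clock genes, 9 were lower and 2 higher with TGF-β in Co.vec cells (mean -0.67, camera p = 0.00159; p = 0.0099 with an estimated correlation) and 9 and 3 in LETS1 cells (-0.78). PER2 (-1.48 and -1.07) and DBP (-2.69 and -2.98) fell and CRY1 (1.05 and 0.94) rose in both, where no time-matched series was held.

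Non-coding genes higher with LETS1 in both ligand states included LINC02532 (ENSG00000235142, chromosome 6, 106717452 to 106787541), which rose from 12.4 to 22.3 CPM in buffer and from 7.50 to 14.2 CPM with TGF-β (log2 fold change 0.85 and 0.92), and LINC00973 (0.58 and 0.37). None of them can be called LETS1 from the tables used here.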
